A study of Mus musculus with 2 samples.

How the data were processed

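Cells were measured by BD Rhapsody whole transcriptome single-cell RNA sequencing. Basolateral amygdala was dissociated with pronase and actinomycin D, which blocks transcription, and sorted for tdTomato and Hoechst viability, with tissue of 3 mice pooled per treatment, per the labels' protocols. The values used were the deposited counts of unique molecules per cell and gene after the pipeline's RSEC error correction, written by the BD WTA Rhapsody Analysis Pipeline 1.9.1, per the file headers. The reads were assigned to GRCm38, per the submitters' processing notes. Both tables had a column for a tdTomato sequence, per the file headers. Which annotation the authors counted on, and how the pipeline's cell calling was set, are not given in the sources used here. Gene positions were taken from the GENCODE vM21 annotation of GRCm38 by gene symbol.

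The vehicle table held 2925 barcodes and 23139 gene columns, and that of FGF21 held 2455 barcodes and 23102 gene columns. A gene without a column in a table was treated as having 0 UMIs there, over a union of 25120 genes, 21121 of which had a column in both. The median barcode had 3794 UMIs in the vehicle and 5805 in the FGF21 table. Cells were kept with at least 500 UMIs, at least 300 genes and at most 25% mitochondrially encoded UMIs. This left 2354 vehicle and 1951 FGF21 cells. Scrublet in scanpy, run per library, called 17 and 16 doublets (0.767% of cells), which were removed. The barcodes left out by the filter, 571 vehicle and 504 FGF21, had median mitochondrial shares of 42.6% and 42.2%.

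The 4272 cells of both libraries were clustered together without integration, on log-normalised counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 16 clusters. Clusters were named from marker lists of 19 cell types fixed before the data were examined. The naming rule was set after the clusters were seen: the best mean marker z-score had to exceed the next class by 0.5, with at least 3 of the markers found in 10% of the cluster's cells. It left 1 cluster unnamed, with 0.128% of vehicle and 0.517% of FGF21 cells. Names end in "-like" because they rest on these markers. Microglia-like, oligodendrocyte precursor-like and astrocyte-like cells had at least 50 cells in each library and were compared. Neuron-like cells were too few.

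UMIs were summed over the cells of a class and divided by the class total to give CPM. Ratios of the FGF21 to the vehicle library had exact conditional-binomial 95% intervals, and shares had exact Clopper-Pearson intervals. Log2 ratios used a pseudocount of 0.5 UMIs. No test or p-value was computed, because each treatment had 1 library and cells are not replicates. Ratios against 0 UMIs were computed with a floor of 3 UMIs, which is not an interval limit. For a share of 0 cells the upper limit of the exact interval is given. Counts of genes at least 2-fold apart covered genes with at least 50 UMIs over both libraries.

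Genes were named by a rule fixed before the data were examined. In each compared class it took the 8 highest and 8 lowest ratios among genes with at least 50 UMIs, a UMI in at least 10% of cells where higher, and at most 20% of UMIs in 1 cell. Mitochondrially encoded, ribosomal protein and haemoglobin genes were left out of that ranking. It also took the 4 members of a fixed list with the most UMIs and all members of the FGF receptor complex list. Zbtb16, Mt1 and Mt2 were followed into other classes after their values were seen, and Csf1r, Klf9 and Mt3 are among the most abundant members of their lists. The gene lists were likewise fixed beforehand: 26 were ranked, and 1 list of sex-linked genes served to describe the pools. A list's median over members with at least 20 UMIs was set against 10000 random lists of the same size, matched in 20 expression bins. Its percentile describes these libraries and is not a test.

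The background share of a library was estimated, after the data were seen, from the level of marker lists in classes that should lack them, divided by their level in all used cells. Pairs of oligodendrocyte precursor-like cells with astrocyte or oligodendrocyte markers were left out because the types share genes. Mural-like cells with astrocyte markers were left out after this pair was seen at 2.99 and 1.97 times the library level. The reason for leaving that pair out is not reported here. Of the remaining 18 pairs, the 5 with erythroid markers were kept apart for a separate share of 27.4% in the vehicle and 42.1% in the FGF21 library. The median of the other 13 was taken, and the share times the library's profile was subtracted from each class sum. A background above 100% of a gene's UMIs means that the profile predicted more UMIs than were found.

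The ratio and subtraction steps were tested on simulated microglia-like counts. Intervals covered the true ratio for 95.7% of 11475 genes, and 0.0443% of 11282 unchanged genes came out at least 2-fold apart. Genes changed by folds of 2.0, 4.0, 0.5 and 0.25 were recovered at 1.5-fold in 100.0%, 100.0%, 97.9% and 100.0% of cases. Background shrank their log2 ratios by a mean of -0.45 before subtraction and -0.01 after it (172 genes). Over 9282 genes the median absolute error of the log2 ratio was 0.111 without subtraction and 0.115 with it. The simulated counts held counting error only. The subtraction used the same share and library profile that had been added, so subtraction with an estimated share was not tested.

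The alternatives fixed beforehand were a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), no filter, doublets kept, gene minimums of 20 and 200 UMIs (50 for lists), TMM scaling, CPM without mitochondrial and ribosomal genes, a mean over cells, Leiden resolutions 0.5 and 2, and cells thinned to 2000 UMIs. Under the other resolutions, the stricter filter, no filter and with doublets kept, clusters were not named anew from markers. Each took the main class of most of its cells, a rule also set after the clusters were seen. Background subtraction, a ranking of genes by subtracted ratio, and subtraction with a share from erythroid genes, were added after the data were seen. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with seed 0.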

Results

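Single-cell transcriptomes were measured from the basolateral amygdala of adult C57BL/6 mice, a brain region that assigns value to food and other rewards. The mice received either vehicle or FGF21, a hormone secreted mainly by the liver, at 1 mg/kg once per day for 3 days. Tissue of 3 mice was pooled per treatment, dissociated, and sorted for viable cells carrying the red fluorescent protein tdTomato. The series concerns cells that express KLB, or beta-klotho, the co-receptor that lets FGF21 act on FGF receptors. Each pool gave 1 library, so there were no replicates, and every interval covers counting error only. The vehicle library held 2925 barcodes with 11130580 UMIs (unique molecules) and the FGF21 library held 2455 barcodes with 14585503 UMIs. After filtering, 2337 vehicle cells with a median of 4232 UMIs and 1935 FGF21 cells with a median of 6838 UMIs were compared.

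The sorted cells were mostly glia. Microglia-like cells, the resident immune cells of the brain, formed the largest class in both libraries, followed by oligodendrocyte precursor-like cells, the progenitors of myelinating cells. Microglia-like cells made up 60.6% of vehicle cells (95% interval 58.6 to 62.6) and 45.9% of FGF21 cells (43.7 to 48.1). Oligodendrocyte precursor-like cells made up 17.5% (15.9 to 19.1) and 31.8% (29.7 to 33.9), and astrocyte-like cells 4.24% (3.46 to 5.13) and 9.92% (8.63 to 11.3). Mural-like cells, the pericytes and smooth muscle of small vessels, went the other way, with 7.74% (6.69 to 8.90) of vehicle and 2.07% (1.48 to 2.80) of FGF21 cells.

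Mature oligodendrocyte-like cells accounted for 1.75% of vehicle and 4.24% of FGF21 cells. Erythroid-like, border macrophage-like, endothelial-like, choroid plexus-like, leukocyte-like and fibroblast-like cells each stayed under 2% of either library. Neurons were nearly absent from the sort, with 9 neuron-like vehicle cells (0.385%) and 18 neuron-like FGF21 cells (0.930%). One cluster of 3 vehicle and 10 FGF21 cells, led by the mitotic genes Top2a and Mki67, could not be assigned to a type. The sort for tdTomato and viability set which cells were loaded, and the libraries differed in depth, so these shares describe the sorted suspensions and not the tissue.

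**Figure D1:**
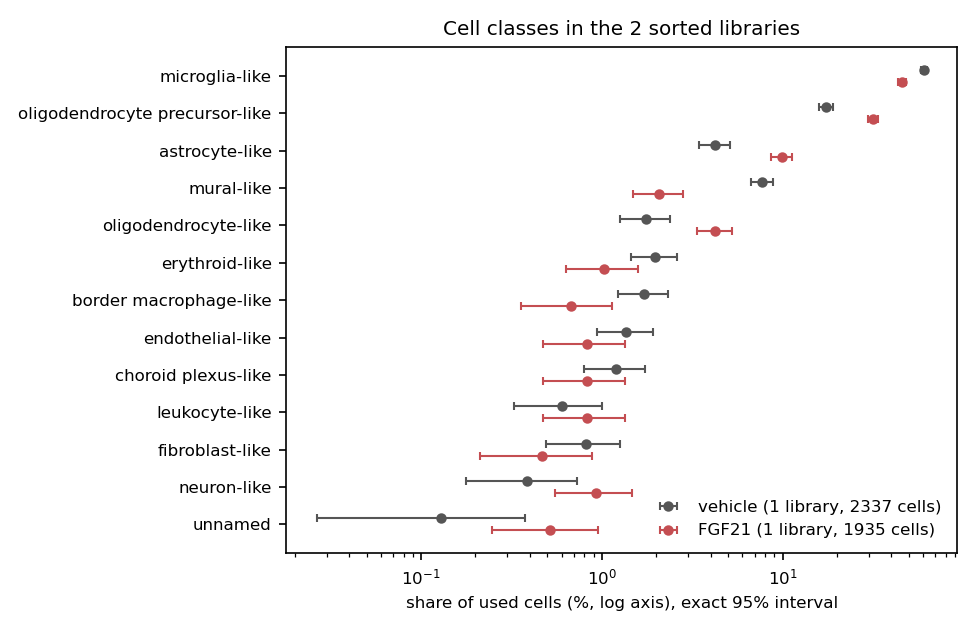
Share of used cells in each class on a log axis in percent, with exact 95% intervals, for 1 vehicle library (2337 cells) and 1 FGF21 library (1935 cells). Microglia-like and mural-like cells took larger shares of the vehicle library, and oligodendrocyte precursor-like, astrocyte-like and oligodendrocyte-like cells took larger shares of the FGF21 library.

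The transcript of the co-receptor itself was hardly detected. Klb (chromosome 5, 65348314 to 65384007, GRCm38) had 3 UMIs in the vehicle library, in 1 oligodendrocyte precursor-like, 1 fibroblast-like and 1 microglia-like cell. It had no column among those of the FGF21 table, which was read as 0 UMIs, so Klb could not be compared between treatments. The tdTomato reporter was present in both libraries, with 766 UMIs in 553 vehicle barcodes and 1083 UMIs in 698 FGF21 barcodes. Of the compared classes astrocyte-like cells had the highest level: astrocyte-like cells had 216 CPM (UMIs per 1000000 UMIs of the class) in the vehicle library and 201 in the FGF21 library, against 66.0 and 75.0 in oligodendrocyte precursor-like and 45.5 and 47.6 in microglia-like cells. The background estimated below accounted for 11.5%, 32.1% and 47.9% of these tdTomato UMIs.

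A tdTomato UMI was seen in 44.4% of vehicle and 57.8% of FGF21 astrocyte-like cells, in 33.6% and 44.7% of oligodendrocyte precursor-like cells, and in 16.4% and 24.8% of microglia-like cells. Erythroid-like cells, a shallow class in which the reporter was hardly seen, had a UMI in 1 of 46 vehicle cells (2.17%) and in 0 of 20 FGF21 cells (exact upper limit 16.8%). Median depths were 4194 and 6115 UMIs for astrocyte-like, 6702.5 and 9107 for oligodendrocyte precursor-like, 4175 and 6015.5 for microglia-like, and 1989 and 2256 for erythroid-like cells, vehicle first. With every cell thinned to 2000 UMIs, the shares were 22.1% and 25.6% of astrocyte-like cells (22 and 28 shallower cells left out), 11.7% and 13.7% of oligodendrocyte precursor-like cells (5 and 4 left out) and 9.58% and 10.4% of microglia-like cells (71 and 22 left out). No thinned erythroid-like cell had one, among 23 vehicle and 11 FGF21 cells with 23 and 9 left out. The exact upper limits of these shares, 14.8% and 28.5%, lay above the thinned microglia-like shares, so a difference between these classes was not shown.

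Of the compared classes, astrocyte-like cells had the highest levels of the FGF receptors, which pair with beta-klotho, at similar levels in both libraries. In astrocyte-like cells Fgfr3 had 1177 CPM in the vehicle and 1053 CPM in the FGF21 library (ratio 0.895, 0.805 to 0.996), Fgfr1 had 268 and 259.6 CPM (ratio 0.969, 0.777 to 1.22), and Fgfr2 had 157 and 160.1 CPM (ratio 1.02, 0.763 to 1.37). The intervals of Fgfr1 and Fgfr2 included equality and that of Fgfr3 ended just below it. In oligodendrocyte precursor-like cells Fgfr1 was at 84.4 and 97.0 CPM (ratio 1.15, 0.987 to 1.34) and Fgfr3 at 59.0 and 80.5 CPM (ratio 1.36, 1.14 to 1.64), with 53.0% of the Fgfr3 UMIs accounted for by the background estimated below. Fgfr2, at 6.94 and 15.1 CPM there, was mostly background as well (103%), as were Fgfr1, Fgfr2 and Fgfr3 in microglia-like cells (101%, 129% and 112%). Microglia-like ratios were 1.17 (0.896 to 1.53) for Fgfr1, 2.70 (1.70 to 4.38) for Fgfr2 and 2.50 (1.98 to 3.18) for Fgfr3.

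Fgfr4 had 1 UMI in the vehicle and 3 in the FGF21 library. The FGF receptor complex list also held the decoy receptor Fgfrl1, the klotho gene Kl and the adaptors Frs2, Frs3, Grb2, Sos1, Gab1 and Ptpn11, of which Kl and Frs3 were not measured in astrocyte-like cells. Kl was lower in microglia-like (ratio 0.539, 0.311 to 0.910) and oligodendrocyte precursor-like cells (0.333, 0.173 to 0.627) and Fgfrl1 higher in microglia-like cells (1.902, 1.38 to 2.65), all mostly background. The median log2 ratio of the whole list was 0.23 in microglia-like, 0.07 in oligodendrocyte precursor-like and 0.19 in astrocyte-like cells, each inside the central 95% of matched random lists. Fgfr1 lies at 25513654 to 25575718 on chromosome 8, Fgfr2 at 130162451 to 133123350 on chromosome 7 and Fgfr3 at 33721674 to 33737068 on chromosome 5.

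Microglia-like, oligodendrocyte precursor-like, astrocyte-like, mural-like and oligodendrocyte-like cells, the classes examined for it, also carried transcripts of other cell types. In the pairs of class and marker list used, these followed the direction of the make-up of the library. The pericyte markers, among them the vessel-wall genes Rgs5 and Vtn, were at 620 CPM in vehicle and 169 CPM in FGF21 microglia-like cells. The oligodendrocyte markers, among them the myelin gene Mbp, were at 1288 CPM and 2118 CPM in the same cells. Pericyte markers in the whole libraries were at 2105 and 443 CPM, and oligodendrocyte markers at 3881 and 6707 CPM. The median of 13 such levels, each divided by the level in the whole library, gave a background share of 29.3% for the vehicle and 32.8% for the FGF21 library. The 5 levels of erythroid markers were kept out of this median and gave 27.4% and 42.1%, so the background was less even over lists in the FGF21 library. This estimate was used below as a measured limit: a gene was called mostly background where over 50% of its UMIs in a class were accounted for by it.

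**Figure D2:**
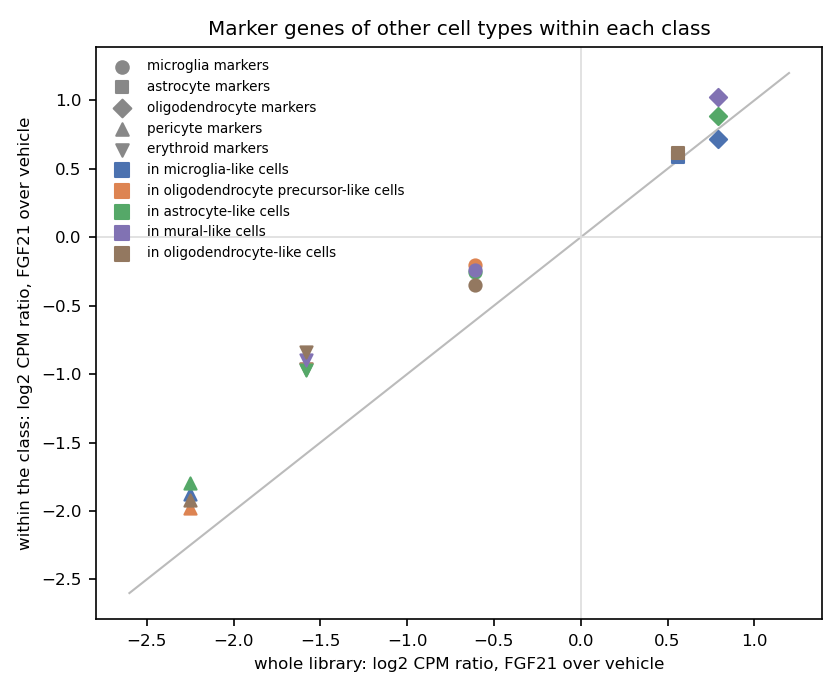
Marker genes of other cell types inside each class examined for them, as log2 CPM ratios of the FGF21 library over the vehicle library (vertical axis), against the same ratio in the whole libraries (horizontal axis). Each point is 1 marker list in 1 class, and the grey line marks equal ratios. Points of a list from different classes lay close together and had the sign of the whole libraries. They ran from pericyte markers at -2.25 to oligodendrocyte markers at 0.79 on the horizontal axis. Erythroid, microglia and pericyte markers, all lower in the FGF21 library, were closer to 0 within the classes than in the whole libraries.

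Within microglia-like cells, the lists of ribosomal protein, nuclear-encoded oxidative phosphorylation and redox and metal binding genes had higher medians in the FGF21 library. The unfolded protein response and heat shock and dissociation lists had lower medians. Most members of each list were less than 1.5-fold apart. Mt1 and Mt2, metallothioneins that bind zinc and copper, were 3.42-fold (3.18 to 3.69) and 4.48-fold (3.85 to 5.23) higher, with 44.0% and 74.3% background. Hspa5, the main chaperone of the endoplasmic reticulum, was at 1240.3 CPM in the vehicle and 709 CPM in the FGF21 library (ratio 0.572, 0.550 to 0.594). Csf1r, the receptor that microglia need for survival, had a ratio of 0.7503 (0.740 to 0.760).

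Of 26 fixed gene lists, 16 had a median outside the central 95% of 10000 expression-matched random lists in microglia-like cells. Of as many random lists 1.30 would lie outside by definition. Members of a fixed list are related and some lists share members, so that number is no test of an excess. Ribosomal protein genes had a median log2 ratio of 0.41, above all 10000 random lists (percentile 100), with 8 of 44 measured members at least 1.5-fold higher and 0 lower. Rplp1, a protein of the ribosomal stalk, had a ratio of 1.49 (1.44 to 1.55). Nuclear-encoded oxidative phosphorylation genes had a median of 0.40 (percentile 100), with 7 of 46 members at least 1.5-fold higher, among their most abundant members Cox8a, a subunit of cytochrome c oxidase, at 1.44-fold (1.33 to 1.55). Glycolysis genes had a median of 0.35 (percentile 99.9), with Gapdh at 1.37-fold (1.30 to 1.45), and redox and metal binding genes a median of 0.42 (percentile 100), with the ferritin light chain Ftl1 at 1.36-fold (1.29 to 1.44).

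The unfolded protein response list had a median of -0.44 in microglia-like cells, with 2 of 16 members at least 1.5-fold lower and 1 higher, and with Hspa5 and Hsp90b1, another chaperone of the endoplasmic reticulum (ratio 0.789, 0.766 to 0.812), among its most abundant members. The heat shock and dissociation list had a median of -0.51, and both lay below all random lists, with 7 of 17 heat shock members at least 1.5-fold lower. Immediate early genes had a median of -0.25 (percentile 0.795, and 8.16 after background subtraction, inside the central range), with Jun, a subunit of the AP-1 transcription factor, at a ratio of 0.512 (0.469 to 0.559), whereas its more abundant relative Jund had a ratio of 1.23 (1.17 to 1.29). Insulin and mTOR signalling genes had a median of -0.25 (percentile 0.110), and homeostatic microglia genes a median of -0.28 (percentile 0.620) with 0 of 14 members at least 1.5-fold apart. The homeostatic list also lay inside after subtraction, at -0.17 (percentile 5.51). Myelin (1.04), cholesterol synthesis and lipid carrier (0.55), synaptic vesicle release (0.52), voltage-gated potassium channel (0.63), metabotropic glutamate receptor (0.74) and AMPA, NMDA and kainate receptor (0.40) genes also had medians above the central range, at percentiles from 98.2 to 100, and their median members were, in this order, 86.0%, 65.2%, 55.8%, 89.0%, 130.1% and 94.8% background. Metabotropic glutamate receptors (percentile 95.1) and immediate early genes (3.56) each fell inside under an alternative, and synaptic vesicle release after subtraction (94.5).

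FGF and ERK feedback targets, which are induced by growth factor signalling and restrain it, had a median of 0.33 in microglia-like cells (percentile 99.4), with a median member at 64.1% background. After background subtraction, with 7 members left, the median was -0.42, below the central range (percentile 0.16). Dusp6, a phosphatase that inactivates ERK, had a ratio of 0.672 (0.640 to 0.706), and the ETS factor Etv5 a ratio of 1.53 (1.41 to 1.66). Medians inside the central 95% were found for GABA receptors (0.31), sodium, calcium and HCN channels (0.30), neuropeptides (0.65), monoamine, opioid and peptide receptors (-0.25), mitochondrially encoded genes (0.16), interferon response and antigen presentation (0.11), microglial activation (-0.14), circadian clock (-0.18) and glucocorticoid response (-0.05) genes. After subtraction the clock list lay outside, at -0.36 (percentile 0.700), and under an alternative so did microglial activation (0.480) and neuropeptides (98.4).

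Most of the genes furthest apart in microglia-like cells were mostly background. The 8 highest ratios belonged to Mt2, Eef1a2, a translation elongation factor of neurons and muscle (4.88-fold, 3.88 to 6.19), Scara3, Fbxo2, the myelin gene Mog, the engulfment receptor Megf10, Tceal5 and Pantr1. The 8 lowest belonged to Abcc9, a potassium channel subunit of pericytes (ratio 0.140, 0.0885 to 0.213), the small heat shock gene Hspb1, Ndufa4l2, Rgs5, P2ry14, Car4, Atp13a5 and Cd248. Over 50% of the UMIs were background for 7 of the 8 highest and 8 of the 8 lowest. Of 11366 genes with at least 50 UMIs, 459 were at least 2-fold higher and 134 at least 2-fold lower in the FGF21 library, and 399 and 74 of them were mostly background. With background subtracted, 98 genes were at least 2-fold higher and 163 lower among the 9081 with at most 50% background. In a ranking by subtracted ratio, chosen after the data were seen, the lowest genes included Kitl, the ligand of the KIT receptor, with 430 vehicle and 160 FGF21 UMIs (ratio 0.392, 0.325 to 0.472, 21.3% background), and Ccnd3, a cell cycle cyclin (0.535, 0.468 to 0.611).

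The class sums behind these ratios held 5829066 UMIs of 1417 vehicle cells and 5526776 UMIs of 888 FGF21 cells. One microglia-like cluster was 98.2% vehicle cells and the other 99.0% FGF21 cells, so the libraries barely shared a microglia-like cluster. The ratios compare the libraries and cannot be assigned to the treatment.

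In oligodendrocyte precursor-like cells, the lists of metabolic and ribosomal genes again had medians slightly above 0, the chaperone gene Hspa5 was lower, and 1 transcription factor stood apart. Zbtb16, a zinc finger repressor also known as PLZF (chromosome 9, 48654297 to 48836222), had 255 UMIs in the vehicle and 57 in the FGF21 library, a ratio of 0.112 (0.0822 to 0.149), with 16.7% background. Mt2 was 3.28-fold (2.80 to 3.87; 57.6% background) and Mt1 2.52-fold (2.30 to 2.76) higher, while Hspa5 had a ratio of 0.528 (0.503 to 0.554). Ccnd1, the cyclin that drives entry into the cell cycle, was at 665 CPM in the vehicle and 999.7 CPM in the FGF21 library (ratio 1.503, 1.43 to 1.58).

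Of 26 lists, 13 had medians outside the central 95% in oligodendrocyte precursor-like cells. FGF and ERK feedback targets had a median log2 ratio of 0.18 (percentile 99.5), with 2 of 18 members at least 1.5-fold higher and 0 lower, and 0.26 after background subtraction. Their most abundant members were Ccnd1, Spred1, an inhibitor of Ras signalling (ratio 1.13, 1.04 to 1.22), Etv5 (1.14, 1.05 to 1.23) and Phlda1 (1.21, 1.11 to 1.31). Medians were 0.24 for ribosomal proteins, 0.17 for nuclear-encoded oxidative phosphorylation, 0.28 for glycolysis, 0.18 for redox and metal binding, 0.43 for cholesterol synthesis and lipid carriers and 0.28 for the glucocorticoid response, at percentiles from 99.9 to 100. Few members were far apart: at least 1.5-fold higher were 2 of 44 ribosomal (1 lower), 2 of 46 oxidative phosphorylation, 3 of 20 glycolysis and 2 of 22 redox genes (1 lower). Of cholesterol and lipid carrier genes 4 of 20 were higher, and of glucocorticoid response genes 1 of 12 was higher and 2 were lower. Gapdh had a ratio of 1.45 (1.34 to 1.56), and Clu, a lipid-binding secreted chaperone, a ratio of 1.41 (1.33 to 1.498).

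The unfolded protein response list had a median of -0.28 in oligodendrocyte precursor-like cells, below all random lists, with 4 of 16 members at least 1.5-fold lower and 1 higher, although the abundant chaperones Calr (0.987, 0.946 to 1.03) and Canx (0.987, 0.939 to 1.04) were level. Also lower were sodium, calcium and HCN channels, with a median of -0.17 (percentile 1.56, but up to 2.965 under the alternatives), with the neonatal sodium channel Scn3a at 0.847 (0.757 to 0.949). Glutamate receptor lists were higher, with medians of 0.21 for AMPA, NMDA and kainate receptors and 0.45 for metabotropic receptors (percentiles 99.9 and 99.5), although their most abundant members, the AMPA subunit Gria2 (0.934, 0.891 to 0.978) and the metabotropic receptor Grm5 (1.06, 0.954 to 1.18), were close to 1. After subtraction both lists lay inside the central range, at percentiles 94.9 and 77.4. Myelin genes had a median of 0.81, which was -0.08 after background subtraction with 4 members left, and homeostatic microglia genes a median of -0.37 with a median member at 109% background. The heat shock and dissociation list (-0.14), immediate early genes (-0.17), interferon response and antigen presentation (0.18), microglial activation (-0.17), circadian clock (0.11), insulin and mTOR signalling (-0.13), mitochondrially encoded genes (-0.06), synaptic vesicle release (0.13), voltage-gated potassium channels (-0.05), GABA receptors (-0.09), neuropeptides (-0.21) and monoamine, opioid and peptide receptors (-0.31) lay inside. After subtraction mitochondrially encoded genes (-0.20, percentile 0.330) and GABA receptors (-0.23, percentile 1.15) lay outside, and under an alternative so did heat shock and dissociation (0.725) and synaptic vesicle release (97.9).

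The 8 highest ratios in oligodendrocyte precursor-like cells belonged to St6galnac5, a sialyltransferase (4.89-fold, 2.55 to 10.5), 1810024B03Rik, the smooth muscle actin Acta2, Sec24d of the vesicle coat, Mt2, Gpr37, Klf16 and the astrocyte enzyme Aldh1l1. Of these 5 were mostly background, among them St6galnac5 (80.1%, with 10 vehicle and 98 FGF21 UMIs). The 8 lowest belonged to Zbtb16, Casq2, the interferon-induced Ifitm1, Hspb1, Ecm2, Rgs5, Higd1b and Abcc9, of which all but Zbtb16 were mostly background. Of 11627 genes, 134 were at least 2-fold higher and 120 at least 2-fold lower, and 47 and 82 of them were mostly background. With background subtracted, 166 were higher and 68 lower among 10484 genes.

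The class sums held 2880743 UMIs of 408 vehicle cells and 5773904 UMIs of 615 FGF21 cells. One cluster with Stk32a and Zbtb16 among its leading genes was 76.2% vehicle cells, one led by Inka2 was 97.1% FGF21 cells, and one led by Enpp6 and Bmp4, genes of cells about to make myelin, held 33 vehicle and 38 FGF21 cells.

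In astrocyte-like cells the glycolysis and nuclear-encoded oxidative phosphorylation lists again had higher medians in the FGF21 library, while the ribosomal list was mostly background. At least 1.5-fold higher were 5 of 18 glycolysis and 3 of 46 oxidative phosphorylation members, and 0 were as much lower. Intervals of single genes were wider than in the other compared classes. Mt1 was 1.54-fold (1.42 to 1.67), Mt2 1.37-fold (1.26 to 1.497) and Mt3, the brain metallothionein, 1.28-fold (1.15 to 1.42) higher, all with under 10% background. Gapdh was 1.38-fold (1.22 to 1.57) higher, whereas Aldoc, the astrocyte aldolase, had the same level in both libraries (2735 and 2731 CPM, ratio 0.998, 0.932 to 1.07). Apoe, the main lipid carrier of the brain, had a ratio of 0.875 (0.831 to 0.922), and Klf9, a glucocorticoid-induced transcription factor, a ratio of 0.677 (0.554 to 0.831).

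Of 24 lists, 7 had medians outside the central 95% in astrocyte-like cells. Higher medians were 0.41 for ribosomal proteins, with 14 of 44 members at least 1.5-fold higher, 1 lower and a median member at 57.5% background, 0.28 for nuclear-encoded oxidative phosphorylation, 0.35 for glycolysis and 1.22 for myelin genes, which had a median member at 80.9% background, all at percentiles from 99.9 to 100. Lower medians were -0.30 for the unfolded protein response (percentile 0.105), which was -0.19 and inside the central range after background subtraction, -0.27 for heat shock and dissociation (percentile 0.660), which was 0.10 after it, and -0.40 for homeostatic microglia genes with a median member at 90.8% background. Inside lay redox and metal binding (0.21), cholesterol synthesis and lipid carriers (0.20), FGF and ERK feedback targets (0.07), immediate early genes (0.31), insulin and mTOR signalling (-0.15), circadian clock (-0.03), glucocorticoid response (-0.17), mitochondrially encoded genes (0.03), AMPA, NMDA and kainate receptors (0.27), metabotropic glutamate receptors (0.24), GABA receptors (-0.15), voltage-gated potassium channels (-0.14), sodium, calcium and HCN channels (0.20), synaptic vesicle release (0.29), interferon response and antigen presentation (-0.03) and microglial activation (-0.50). After subtraction redox and metal binding (0.31, percentile 99.3) and immediate early genes (0.64, percentile 97.8) lay outside. Under an alternative so did redox and metal binding (99.3), cholesterol synthesis and lipid carriers (99.8), synaptic vesicle release (97.9) and insulin and mTOR signalling (0.05). Heat shock and dissociation genes fell inside under an alternative (percentile 30.85).

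The highest ratios in astrocyte-like cells rested on few vehicle UMIs. Kif3c, a kinesin motor subunit, had 0 vehicle and 51 FGF21 UMIs. Against a floor of 3 vehicle UMIs its ratio was 5.74, and the lower limit of its interval was 4.50, with 45.0% background. Cdh13, a cadherin, had 2 and 64 UMIs (10.8-fold, 2.87 to 91.1) and was mostly background (92.1%). Eef1a2 had 4 and 94 (7.93-fold, 3.00 to 29.7), and Naa38 had 3 and 49 (5.51-fold, 1.78 to 27.7). Myrf, Phf21b, Ppp2r5e and the immediate early gene Nr4a1 completed the 8. The 8 lowest were Rgs5, Otulinl, Nrros, Abca9, Vtn, the collagen gene Col4a1, Aff1 and Wdr60, with ratios from 0.167 (0.116 to 0.238, 97.9% background) for Rgs5 to 0.338 (0.186 to 0.612) for Wdr60. Of the 8 highest 3, and of the 8 lowest 5, were mostly background. Of 6128 genes, 197 were at least 2-fold higher and 88 at least 2-fold lower, and after background subtraction 354 and 208 among 5042 genes. The sums held 406899 UMIs of 99 vehicle and 1205590 UMIs of 192 FGF21 cells, all in 1 cluster that was 66.0% FGF21 cells.

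**Figure D3:**
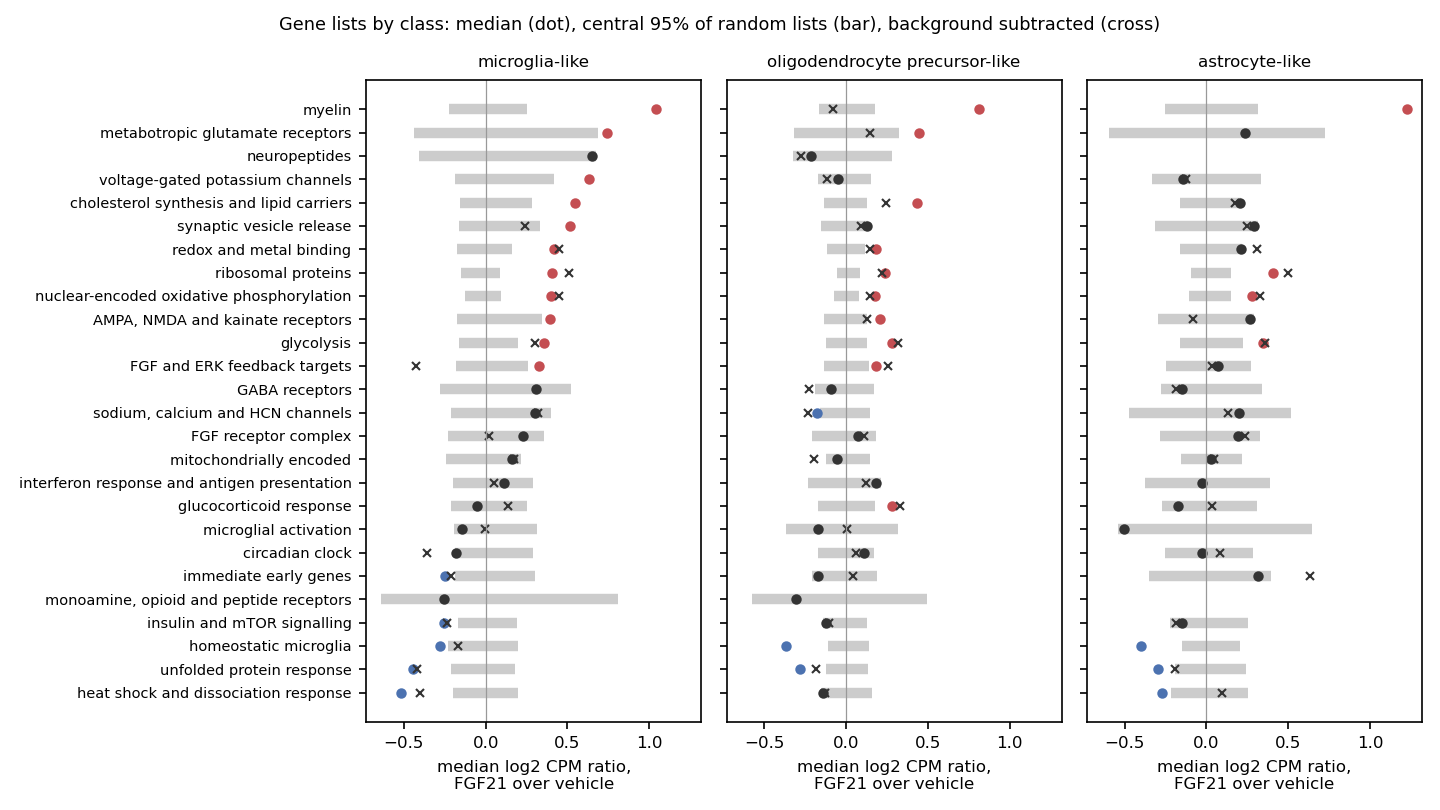
Median log2 CPM ratio, FGF21 library over vehicle library, of each fixed gene list in 3 classes. Dots are list medians (red above and blue below the central 95% of matched random lists, black inside), grey bars are that central range, and crosses are medians after background subtraction where at least 4 members had at most 50% background. Ribosomal protein, oxidative phosphorylation and glycolysis dots lay above and unfolded protein response dots below the grey bars in all 3 classes, and the astrocyte-like unfolded protein response median lay inside the range of random lists after subtraction.

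Zbtb16 and the metallothioneins differed in the same direction in every class examined. Across 9120 genes, which are not independent replicates, the log2 ratios of microglia-like and oligodendrocyte precursor-like cells correlated with r = 0.546. The value was 0.439 for microglia-like and astrocyte-like cells (3232 genes) and 0.442 for oligodendrocyte precursor-like and astrocyte-like cells (3283 genes). Among genes with at most 50% background, r was 0.498, 0.477 and 0.396 before subtraction and 0.204, 0.272 and 0.230 after it. The classes share 2 libraries and their background, so these values do not by themselves show a shared response. Zbtb16 was lower in the FGF21 library in each of 5 classes examined: besides oligodendrocyte precursor-like cells, it had 118 and 10 UMIs in microglia-like cells (ratio 0.0894, 0.0418 to 0.170, 72.9% background), 23 and 7 in astrocyte-like (0.103, 0.0372 to 0.247), 27 and 9 in oligodendrocyte-like (0.124, 0.0514 to 0.272) and 42 and 0 in mural-like cells. In mural-like cells Zbtb16 was 4.203-fold lower against a floor of 3 FGF21 UMIs, and the upper limit of its ratio was 0.306. Mt1 and Mt2 were higher in the same 5 classes, from 1.54-fold and 1.37-fold in astrocyte-like to 4.18-fold (2.99 to 5.85) and 4.90-fold (2.54 to 9.67) in mural-like cells. Mt2 was mostly background in mural-like (81.9%, with 17 and 25 UMIs), microglia-like (74.3%), oligodendrocyte-like (67.6%) and oligodendrocyte precursor-like cells (57.6%). Only in astrocyte-like cells (4.68%) was it not. After subtraction the log2 ratio of Mt2 was 3.09 in microglia-like, 2.96 in mural-like, 1.53 in oligodendrocyte precursor-like and 1.43 in oligodendrocyte-like cells. Vehicle UMIs of Mt2 were few in mural-like (17) and oligodendrocyte-like cells (15).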

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

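Of the tests in this part, those of doublets and of gene length were written before their results were seen; the shared background, fixed free RNA, ribosomal subtraction, library and Zbtb16 tests were chosen after the results were seen.

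Mural-like cells, which were not compared in the report because the FGF21 library held 40 of them, drew attention for contractile genes, 3 of which were singled out after being seen. The smooth muscle marker list was 3.28-fold (3.03 to 3.55) higher in the FGF21 library, with its most abundant members Myl9 at 1.59-fold and Mylk at 1.52-fold. Acta2, the smooth muscle actin, was 13.1-fold (10.6 to 16.4) higher, the actin-binding gene Tagln 14.2-fold (9.21 to 22.7) and the smooth muscle myosin Myh11 5.87-fold (4.23 to 8.23). An Acta2 UMI was found in 9.94% of vehicle and 25.0% of FGF21 mural-like cells, a Tagln UMI in 4.97% and 17.5%, and a Myh11 UMI in 13.8% and 25.0%. Myl9 was found in 80.1% and 90.0%, and Mylk in 85.1% and 87.5%. The intervals count UMIs as independent and are too narrow where few cells hold them. These values do not tell a higher level per cell from a larger share of cells with the genes. The pericyte marker list went the other way in the same cells, with a ratio of 0.790 (0.763 to 0.819).

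Barcodes left out by the cell filter drew attention for some transcripts of neurons and for those of red blood cells. The erythroid marker list was 12.4-fold (12.2 to 12.5) more abundant in left-out barcodes than in used cells of the vehicle library and 11.5-fold (11.2 to 11.7) in the FGF21 library. Bc1, a small noncoding RNA carried into dendrites, was 153.7-fold (143.6 to 165) and 80.4-fold (75.1 to 86.0) more abundant. Camk2a, whose mRNA is also carried into dendrites, was 24.7-fold (21.7 to 28.2) and 22.4-fold (19.4 to 25.9) more abundant, and Kif5a, a neuronal kinesin, 24.2-fold (21.6 to 27.0) and 20.1-fold (18.0 to 22.5). The general neuron marker list was 2.00-fold (1.84 to 2.17) and 1.24-fold (1.13 to 1.36) more abundant, the glutamatergic neuron list 2.70-fold (2.47 to 2.94) and 2.71-fold (2.44 to 3.02), and the GABAergic neuron list less abundant (0.714 and 0.501), so the left-out barcodes were not rich in all neuronal transcripts. Snap25, a synaptic gene with mRNA mainly in the cell body, was 2.73-fold (1.92 to 3.80) and 2.35-fold (1.69 to 3.19) more abundant, the neuronal nuclear protein gene Rbfox3 5.76-fold and 2.81-fold and the neuronal gene Stmn2 4.21-fold and 4.42-fold, and these genes were chosen after their values were seen.

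Marker genes of other cell types moved with the make-up of the library in each class examined for them, not in all classes. The highest over the lowest level of a foreign list, relative to its library, was 1.79 in the library with the wider range. The astrocyte list in mural-like cells (2.99 and 1.97) was left out of this after its values were seen. The bound for calling a shared background was also set after seeing the values, so 1.79 does not decide. In FGF21 microglia-like cells the levels were 0.44 for erythroid and 0.38 for pericyte markers, against 0.33 for astrocyte and 0.32 for oligodendrocyte markers. A single share therefore did not hold equally for every list. Doublets as the whole source are argued against, because the share of microglia-like cells with a foreign UMI was 1.00 of the share expected with even spread. A fixed amount of free RNA per barcode is argued against too, since the 25% of microglia-like cells with the most UMIs had 0.915 of the foreign CPM of the 25% with the fewest. A source that scales with each barcode's depth may remain, and the data do not show at which step it would act.

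The ribosomal protein and nuclear-encoded oxidative phosphorylation lists had higher medians in the FGF21 library in all 3 compared classes, with most members less than 1.5-fold apart. In astrocyte-like cells the ribosomal list was mostly background (57.5% at its median member). Shared background is argued against in microglia-like cells, where subtraction left the ribosomal median at 1.25 of its uncorrected value. Gene length is left open. The ribosomal median of 0.41 in microglia-like cells was at percentile 100 of lists matched on length and expression, which had a median of 0.10. However, the matched genes stayed longer (median 2572 against 1736.5 bases) and less abundant (median 2601 against 5075.5 UMIs). Log2 ratios also fell slightly with length (Spearman correlation -0.12 over 12881 genes), so the incomplete match cannot exclude length. The treatment cannot be told apart from any other difference between the libraries, such as the pool of mice, the dissociation or the capture, with 1 library per treatment.

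Zbtb16 was lower in the FGF21 library in all 5 classes examined, with 72.9% background in microglia-like cells. Shared background is argued against, because its log2 ratio in oligodendrocyte precursor-like cells was -3.17 after subtraction. A few vehicle cells are argued against by a log2 ratio of -2.68 (-3.15 to -2.25) without the 5% of cells with the most Zbtb16 UMIs, a value added after those cells were found to hold 32.5% of the UMIs, which met neither bound first written. A lower glucocorticoid response is left open: the rest of that list had medians of 0.33 in oligodendrocyte precursor-like (percentile 99.9), 0.0468 in microglia-like and -0.0941 in astrocyte-like cells. Astrocyte-like cells were added to this test after the other classes were seen, and only their negative median kept the question open under the rule used. Members of the list went both ways, from Fkbp5 (0.570) to Ddit4 (1.54) in microglia-like cells and with Klf9 at 0.677 in astrocyte-like and 1.34 in oligodendrocyte precursor-like cells. Fkbp5 was lower in all 5 classes, from 0.143 (0.0616 to 0.307) in oligodendrocyte-like to 0.877 (0.256 to 2.43) in mural-like cells. It was mostly background outside microglia-like cells, and its intervals in astrocyte-like and mural-like cells included equality. An effect of FGF21 on Zbtb16 is a hypothesis that may hold, as may any other difference between the 2 pools.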

How the results depend on the processing

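The background settings below were chosen after seeing the data, and the others beforehand. Of 641 values under the alternatives set beforehand, 621 stayed within their interval or within 1.5 times, 20 moved and 0 reversed. Reversed means a change of sign in a value whose interval excluded equality or a list outside the central 95%; some medians of lists inside it changed sign. Of 93 values under the added ones, 76 stayed, 14 moved and 3 reversed. The difference in oligodendrocyte precursor-like share was 11.2 points with no cell filter. Counts of genes at least 2-fold higher and lower depended on the gene minimum, which changes how many genes are counted, and on background subtraction. With at least 20 UMIs they were 705 and 311 in microglia-like, 273 and 327 in oligodendrocyte precursor-like and 542 and 328 in astrocyte-like cells. With at least 200 UMIs they were 160.0 and 28, 24 and 18, and 15 and 4. The mean over cells gave 297 and 174 in astrocyte-like cells, and the cause was not tested. Background subtraction, with the limit to genes with at most 50% background, gave 98 higher in microglia-like, 68 lower in oligodendrocyte precursor-like, and 354 higher and 208 lower in astrocyte-like cells. With the share from erythroid genes, 79 were higher and 205 lower in microglia-like, 73 lower in oligodendrocyte precursor-like and 171 lower in astrocyte-like cells. The share of higher genes among those 2-fold apart was 77.4% in microglia-like and 52.8% in oligodendrocyte precursor-like cells, 50% and 69.6% with the gene limit alone, and 37.5% and 70.9% with subtraction as well. With subtraction 9 gene lists were outside the central 95% in microglia-like cells, not all of them the same lists. It reversed the medians of FGF and ERK feedback targets in microglia-like cells (-0.42), myelin in oligodendrocyte precursor-like cells (-0.0829) and heat shock and dissociation in astrocyte-like cells (0.10), from the fewer members with at most 50% background. In cells thinned to 2000 UMIs, the log2 ratio of Fgfr1 was 0.71 and of Fgfr2 2.71 in microglia-like cells, and of Fgfr2 -0.40 in astrocyte-like cells, and the cause was not tested. Lists outside the central 95% in every setting fixed beforehand numbered 14 of 26 in microglia-like, 12 of 26 in oligodendrocyte precursor-like and 6 of 24 in astrocyte-like cells, and 7, 8 and 3 of them stayed outside after subtraction. Some of the others had no value after subtraction, for lack of members with at most 50% background, such as myelin in microglia-like and astrocyte-like cells. Klb had 3 UMIs in all, too few to compare, and the cause of this low count was not tested. The 406899 UMIs of vehicle astrocyte-like cells limited single genes there. No paired analysis was possible because each treatment had 1 library.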

Other observations

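The values in this part were chosen after they were seen, and no test beyond the counting intervals was run on them. Classes too small for the comparisons held the highest levels of some FGF pathway genes. Kl, the klotho gene and the co-receptor of a related hormone, FGF23, was at 1273 CPM in vehicle and 1167 CPM in FGF21 choroid plexus-like cells (28 and 16 cells, ratio 0.917, 0.755 to 1.11). Fgfr2 was at 314 CPM in vehicle and 425.5 CPM in FGF21 oligodendrocyte-like cells (41 and 82 cells, ratio 1.35, 1.07 to 1.73). Fgfr1 was at 722 CPM in vehicle and 433 CPM in FGF21 fibroblast-like cells (19 and 9 cells, ratio 0.6002, 0.325 to 1.06). The tdTomato reporter was at 172 and 140.3 CPM in mural-like, at 184 and 195 CPM in endothelial-like, at 202 and 331 CPM in fibroblast-like and at 186 and 91.8 CPM in choroid plexus-like cells (ratio 0.494, 0.248 to 0.930), against 21.1 CPM in vehicle erythroid-like cells.

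Inducible heat shock genes were lower in the FGF21 library where they were counted best. Hspa1b, an inducible chaperone, had 111 UMIs in vehicle and 10 in FGF21 microglia-like cells (ratio 0.0950, 0.0443 to 0.181), and 74 and 2 UMIs in mural-like cells (0.0900, 0.0107 to 0.337). Hspa1a, its neighbour, had 84 and 2 UMIs in mural-like cells (0.0793, 0.00945 to 0.296), and reads of these near-identical genes can be hard to assign. Hsp90aa1, a constitutive and inducible chaperone, had a ratio of 0.314 (0.224 to 0.430) in mural-like and 0.943 (0.898 to 0.990) in oligodendrocyte precursor-like cells.

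Both pools held transcripts of the Y chromosome. Ddx3y, a Y-linked helicase, had 1669 UMIs in the vehicle and 1723 in the FGF21 library, and Xist, the RNA that silences 1 X chromosome in females, had 18 and 14. Differentiating precursors led by Enpp6 and Bmp4 were found in both libraries, with 33 vehicle and 38 FGF21 cells.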
